A study of Mus musculus with 2 samples.

How the data were processed

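Gene expression and hashtag counts were measured by droplet 3' single-cell RNA sequencing (10x Genomics 3' v3.1 chemistry, per the labels' protocols) in 1 capture of thymic cells pooled from 2 mice. The series lists 2 libraries, 1 of mRNA and 1 of hashtags. A single deposited matrix holds both, as whole-number UMI counts per gene and barcode that the authors made before any normalization. Cell Ranger 6.0.1 and the mouse build mm10 (GRCm38) are named in the submitters' processing notes, without a role or order. The aligner settings, the annotation release and the cell calling of the authors are not given in the sources used here. The number of columns of per-sample values that were not used was 0.

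Genotypes were assigned from the hashtag counts. The deposited feature names pair 1 hashtag with the Lta-/- cells and the other with the control cells, and that pairing was used. Those names number the antibodies differently from the labels' protocols, so the direction of the genotype comparisons was taken from the feature names. The cells so labelled Lta-/- had 72 Lta UMIs against 509 in the others, the order that a loss of Lta gives. A cell was assigned when it had at least 10 counts of a hashtag that made up at least 80% of its hashtag counts. The median was 5096 counts of the own hashtag against 30 of the other in Foxp3eGFP cells and 3501.5 against 42 in Lta-/- cells. Cells with both hashtags numbered 184 (3.97%), at a median of 10527.5 UMIs, and 0 cells had no call. From that rate, a further 184.02 doublets within a genotype are expected among the assigned cells (4.13%), which cannot be found by hashtag. Doublet calling by Scrublet as run in scanpy, at an expected rate of 0.04, marked only 1 cell and so removed almost nothing.

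Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, which removed 160 of 4798, and the Scrublet call removed 1 more. Counts were scaled to 10000 per cell, and log-transformed values of 2000 variable genes went into 30 principal components, 15 neighbours and Leiden clustering at resolution 0.6. Foxp3, Il2ra, Lta, Ltb, receptor V(D)J segments and sex-linked marker genes were left out of the variable genes. A cluster was named only from marker lists fixed before the data were examined, with at least 3 markers at least 1.5-fold higher. Several clusters passed more than 1 list, and each name given is that of the list with the most markers higher. Software was Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.

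For each comparison, raw UMIs were summed over the cells of a class or genotype and expressed as counts per 1000000 UMIs (CPM). Ratios have exact conditional binomial (Clopper-Pearson) intervals, shares have Clopper-Pearson intervals and levels have exact Poisson intervals, all at 95%. Cells of 1 mouse are not replicates, so no p-value was computed. In data simulated for the Lta-/- over Foxp3eGFP comparison on 9661 genes, the interval held the true ratio for 95.5% of unchanged genes. It did so for 98% and 92% of 50 genes each changed 0.5-fold and 2-fold, and for 96% of those changed 1.5-fold. The simulated sums were Poisson counts, the model that the interval assumes, so this checked the calculation only. They held no variation between cells or mice, so the coverage in the real data is not known. A ratio against 0 counts was computed with 3 counts in place of the 0. Shares of cells with a UMI were also computed after thinning each cell to 3000 UMIs.

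The genes named for each comparison were the 12 largest ratios in each direction among genes with at least 100 UMIs in both classes together and 50 CPM in the higher class. Foxp3, Il2ra, mitochondrial, ribosomal protein, Gm and Rik genes, sex-linked marker genes and V(D)J segments were left out of that rule, and members of the fixed lists could be named as well. For clusters, the 10 genes with the largest ratio to all other cells were taken. Gene names that fall outside these rules were chosen after their values were seen and are said to be so. There were 15 fixed lists (Treg core, strong T cell receptor signal, TNFR superfamily and NF-kB, IL-2 and STAT5, IL-4 and STAT6, lymphotoxin and TNF ligands, maturation and egress, immature CD4 thymocyte, apoptosis, effector and recirculating Treg, helper lineage regulators, chemokine receptors, proliferation, interferon response, dissociation stress) and 17 cell type marker lists. A list member counted as higher or lower at a ratio of at least 1.5 with at least 50 UMIs. Foxp3 and Il2ra were left out of every list in the comparisons between classes by their UMIs. Positions came from a RefSeq gene table of the same build (GRCm38), which placed 97.2% of the 9661 genes with at least 100 UMIs.

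Alternatives covered looser and stricter cell filters, thinning, a class threshold of 2 UMIs, cells of 1 mouse alone, clusters left out, other weightings of cells and list members, other hashtag thresholds and other cluster settings. T cell receptor sequences and raw reads were not used here.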

Results

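Single-cell 3' RNA profiles were collected from thymic regulatory T (Treg) lineage cells of 2 mice. The control mouse carried the Foxp3eGFP reporter, which marks cells that express the Treg transcription factor Foxp3. The other mouse carried the reporter and lacked Lta, which encodes lymphotoxin alpha, a secreted member of the tumour necrosis factor family. CD4+CD8- CCR6- CD3e+ thymocytes positive for CD25 (the IL-2 receptor alpha chain, encoded by Il2ra), for eGFP or for both were sorted, 20000 per genotype. The sorted cells carried a genotype-specific antibody hashtag and were captured together in 1 well. The matrix held 4798 barcodes and 32285 genes, and 4637 cells were kept. Of these, 2209 were assigned to the Foxp3eGFP mouse, with 15010916 UMIs in total and a median of 5547 per cell. Another 2244 were assigned to the Lta-/- mouse, with 14054827 UMIs and a median of 5395. Both hashtags were present in 184 cells, which entered no genotype comparison but were kept in the comparisons by Foxp3 and Il2ra. A droplet with more than 1 cell can place Foxp3 of a cell beside Il2ra of another, and so add to the cells with both. Doublets within a genotype, which hashtags cannot find, can do the same. There was 1 mouse per genotype, so no value below has a replicate error and no test was made. The intervals given are exact 95% intervals that cover counting error only. A log2 ratio is that of counts per 1000000 UMIs (CPM) between pooled cells.

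The first question was which cell states the sorted population held. The cells fell into 9 clusters, numbered from 0, when the gate genes were left out of the clustering. Cluster 5 was mature Treg-like, with 10 of 11 markers at least 1.5-fold higher, and held 21.1% of the cells. It also had 8 of 12 interferon-responding and 6 of 10 mature CD4 single-positive markers higher. It was led by Rgs1, Lrrc32, Gpr83, Nrp1 and Ctla4, of which Lrrc32 encodes the receptor that presents latent TGF-beta and Ctla4 an inhibitory receptor. Clusters 0 and 1 were agonist-signalled precursor-like, with 15.5% and 14.2% of the cells. Cluster 0 was led by Ccl4, Lad1, Xcl1, Gadd45b and Tnfrsf9, and cluster 1 by the immediate early genes Egr3, Nr4a1, Egr1 and Nr4a3, which respond to T cell receptor signals. Cluster 2 was mature CD4 single-positive-like, with S1pr1, the receptor used for thymic exit, and Gimap3 among its leading genes. Cluster 4 had the same name on 3 higher markers, Il7r, Igfbp4 and Dapl1. Cluster 3 was immature CD4 single-positive-like. It was led by Ccr9, a chemokine receptor of immature thymocytes, at 12.1 times its level in the other cells, and all 8 immature markers were at least 1.5-fold higher in it. Cluster 6 was proliferating-like, with all 12 proliferation markers higher and a median of 14570 UMIs per cell. Clusters 7 and 8 stayed unnamed, though each passed several lists. Cluster 7 had 13 of 14 effector or recirculating Treg markers and 9 of 10 innate-like T markers higher. Its 10 leading genes mixed 5 of the former (Cxcr3, S100a4, S100a6, Maf and Itgae) with the innate-like T genes Cxcr6 and Klrd1. Cluster 8, with 117 cells, mixed plasma cell genes (Iglc2, Mzb1, Jchain), macrophage genes (Lyz2, C1qb) and, outside its 10 leading genes, 10 of 11 markers of double-positive thymocytes. All 12 proliferation markers were at least 1.5-fold higher in cluster 8 as well. The number of clusters rested on the resolution and was 17 at a Leiden resolution of 1.0.

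The second question was how the transcripts of the sort markers were spread over these states. Foxp3 lies on chromosome X at 7579676 to 7595243 and Il2ra on chromosome 2 at 11642792 to 11693194 (GRCm38). Among all kept cells, 11.3% (10.4 to 12.2) had a UMI of Foxp3 only, 13.3% (12.3 to 14.3) of Il2ra only, 9.19% (8.37 to 10.1) of both and 66.2% (64.9 to 67.6) of neither. After thinning every cell to 3000 UMIs in the 4324 cells that had as many, the shares were 8.65%, 11.6%, 4.72% and 75.0%. The cells had been sorted on protein, so a cell without a UMI is not a cell without the protein. Cluster 5 held the most of both transcripts, with Foxp3 detected in 47.9% (44.7 to 51.1) and Il2ra in 53.6% (50.4 to 56.8) of its cells. Foxp3 was next most frequent in cluster 2, at 25.8%, where Il2ra was found in 7.39%. The order was the opposite in cluster 0, with Il2ra in 30.1% and Foxp3 in 8.32% of the cells. The Ccr9-high cluster 3 was nearly free of both, at 0.641% (0.0777 to 2.30) for Foxp3 and 1.60% (0.522 to 3.70) for Il2ra at a median of 5238 UMIs per cell. Those shares, the lowest of any cluster, were taken as a rough background that free RNA can give, though these cells too had passed the sort. Cluster 4 was also low, at 2.94% for Foxp3 and 4.17% for Il2ra. The mixed cluster 8 had 5.98% and 26.5%, so no cluster is a known negative. Its shares were 3.03% and 12.1% after thinning, on only the 66 of its 117 cells with at least 3000 UMIs. The proliferating-like cluster 6 had shares of 7.33% and 7.69%, which fell to 1.48% and 3.70% after thinning.

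**Figure D1:**
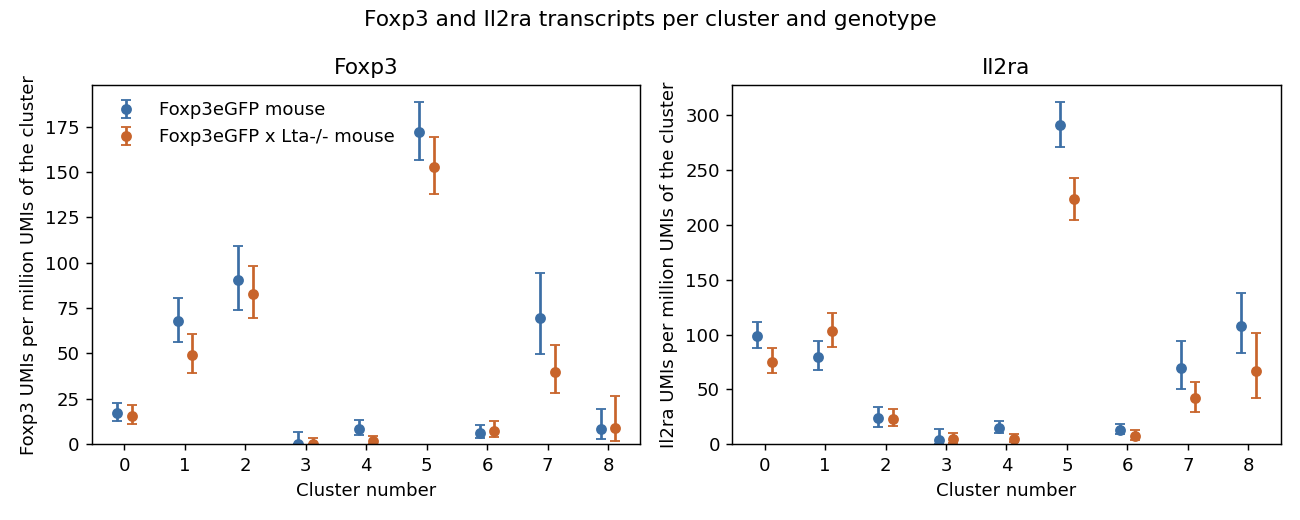
Foxp3 (left) and Il2ra (right) in CPM of each cluster, for the cells of the Foxp3eGFP mouse and of the Lta-/- mouse, with exact 95% Poisson intervals. Both genes were highest in the mature Treg-like cluster 5 and near 0 in the Ccr9-high cluster 3.

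Cells with Il2ra only were compared with cells that had both transcripts. This is only a loose transcript counterpart of CD25+Foxp3- precursors against CD25+Foxp3+ cells. The mature Treg-like cluster 5 held 240 of the 615 Il2ra only cells, and Foxp3 was detected in only 47.9% of its cells. Cells whose Foxp3 was missed can therefore count as Il2ra only. Genes of strong T cell receptor signals differed in both directions between the Il2ra only cells and those with both transcripts. The thymic exit genes past 1.5-fold were lower in the Il2ra only cells. The summed T cell receptor signal list had a log2 ratio of 0.21 (0.18 to 0.25), with 5 of 22 members at least 1.5-fold higher and 3 lower. Ikzf2 alone made up 32.6% of that sum, and the median of 0.17 lay at percentile 92.2 of random lists matched on expression. The dissociation stress list, which holds other immediate early genes, was at 0.30 (0.27 to 0.33) in the same comparison. Bcl2l11, which encodes the death inducer Bim, was at 1.51 (1.26 to 1.78), Tnfrsf9 at 1.43 (1.28 to 1.59) and Nfkbid at 0.88, while Egr1 was at -1.20 (-1.46 to -0.94) and Egr3 at -0.95. The maturation and egress list was at -0.39 (-0.41 to -0.37), with 6 of 20 members lower and 0 higher. S1pr1 was at -0.97 (-1.11 to -0.84) and Klf2, a transcription factor that regulates S1pr1, at -0.73. Of the Treg core list, 11 of 16 measured members were lower and 1 higher (summed -0.16, -0.19 to -0.13), among them Gpr83 at -1.29, Ctla4 at -1.12 and Lrrc32 at -1.07. The IL-2 and STAT5 list was at -0.42 (-0.46 to -0.37), with 5 of 15 members lower, including Il2rb at -0.79 (-0.98 to -0.61) and Socs2 at -0.97. The proliferation list was at 0.70 (0.65 to 0.74), with 13 of 20 members higher.

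By the fixed rule, the highest genes of the Il2ra only cells were Plac8 (3.43), Dntt (3.16), Ly6d (3.13), Gzma (3.00), Nrgn (2.27), Hist1h1b (2.00), Cd40lg (1.75), Mrps28 (1.74), Marcksl1 (1.62), Marcks (1.60), Bcl2l11 (1.51) and Pclaf (1.44). The lowest, beside those named above, were Gsta4 (-1.37), Rgs1 (-1.32), Cd55 (-1.14), Itih5 (-1.10), then Tmem71 and Mbnl3, and Samhd1 (-0.98). Cluster 8 held 30 of the 615 Il2ra only cells and 1 of the 426 cells with both. Dntt was among the double-positive thymocyte markers higher in cluster 8, so its ratio may rest largely on those cells. Markers of other cell types were also higher in the Il2ra only cells, at 1.51 for gamma-delta T cells, 1.28 for NK cells or innate lymphoid cells and 0.73 for double-positive thymocytes. Gzma was at -1.30 after thinning, and Hist1h1b at -0.71 in Lta-/- cells alone. Without cluster 8, Gzma was at 0.058, Plac8 at 1.63 and Ly6d at 0.98, Nrgn and Cd40lg were at 2.33 and 1.84, and the proliferation list was at 0.37. Cluster 5 held 284 of the cells with both, and clusters 5 and 0 held 240 and 187 of the Il2ra only cells.

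Cells with Foxp3 only, a loose transcript counterpart of CD25-Foxp3+ precursors, were set against the same cells with both. Cluster 5 held 184 of the 524 Foxp3 only cells, and Il2ra was detected in 53.6% of its cells. Cells whose Il2ra was missed can therefore count as Foxp3 only. The summed T cell receptor signal, NF-kB and IL-2 response lists were lower in the Foxp3 only cells. The T cell receptor signal list had a summed log2 ratio of -0.11 (-0.16 to -0.071), a median of -0.44, and 10 of 21 members lower with 0 higher. Nr4a3 was at -2.56 (-3.17 to -1.99), Egr3 at -2.00, Myc at -1.80 (-2.22 to -1.39) and Nr4a1 at -1.76 (-2.14 to -1.39). When a class needed 2 UMIs of its gene, the summed value was 0.055, so its direction rested on how the class was defined. The dissociation stress list was lower as well, at -0.19 (-0.22 to -0.15). The maturation and egress list was at 0.093 (0.075 to 0.11), with 0 of 20 members past 1.5-fold. The TNFR superfamily and NF-kB list was at -0.50 (-0.54 to -0.45), with 5 of 19 members lower, including Tnfrsf4 at -0.98 and Rel at -0.89, and Tnfrsf1a higher at 0.76. The IL-2 and STAT5 list was at -0.38 (-0.43 to -0.33), with 8 of 14 members lower, among them Cish, a direct STAT5 target, at -1.15 and Pim1 at -1.07. The Treg core list was at -0.53 (-0.57 to -0.50), with 9 of 16 members lower.

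The lowest genes by rule were Ccl4, with 0 UMIs in Foxp3 only cells against 164 in cells with both, then Xcl1 (-4.22), Nr4a3, Rgs1 (-1.85), Socs2 (-1.80), Myc, Nr4a1, Lrrc32 (-1.63), Mir155hg (-1.60), Gadd45b (-1.58), Lta (-1.29) and Ecm1 (-1.26). The log2 ratio of Ccl4 was -5.77 with 3 counts in place of the 0, and the upper end of its interval was -5.46. In Lta-/- cells alone, Xcl1 turned to 3.28 and S100a4, named next, to -0.14. The highest were Cd74 (2.21), S100a4 (1.35), S100a6 (1.20), S100a11 (1.00), Arhgap20 (0.93), H2afx (0.92), Ube2c (0.89), Hist1h2ap (0.88), Hist1h1b (0.85), Pdk1 (0.84), Mettl9 (0.82) and Pik3ip1 (0.82). Markers of B cells and of myeloid or dendritic cells were higher in Foxp3 only cells too, at 1.38 and 1.12, and without cluster 8 Cd74 was at 0.41. The histone and mitosis genes turned below 0 after thinning, with Ube2c at -1.20, and Ube2c did so without cluster 6 as well. Foxp3 only cells lay mainly in clusters 5 (184 cells) and 2 (154 cells).

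Set directly against the Foxp3 only cells, Il2ra only cells had more of the T cell receptor signal genes and less of the exit genes. The T cell receptor signal list was at 0.33 (0.29 to 0.36), with 14 of 22 members higher and only Egr1 lower, at -1.16. Nr4a3 was at 2.72, Nr4a1 at 2.10, Myc at 2.03 and Nfkbid at 1.98. The dissociation stress list was higher too, at 0.49 (0.46 to 0.52), so handling was not set apart from signalling here. The maturation and egress list was at -0.48 (-0.50 to -0.46), with 12 of 20 members lower, including S1pr1 at -1.17 and Klf3 at -1.02. The TNFR superfamily and NF-kB list was at 0.65 (0.61 to 0.69), with 7 of 19 members higher, among them Tnfrsf9 (CPM of 378 against 134) and Tnfrsf4 (OX40) at 1.22. Of the apoptosis list (0.33, 0.28 to 0.38), the survival genes Bcl2a1d at 2.97 and Bcl2l1 at 2.48 were higher together with Bcl2l11 at 1.41. The lymphotoxin and TNF ligand list was at -0.13 as a sum, which Ltb dominated, and at 0.62 as a median, with Cd40lg at 1.53 and Lta at 0.85 higher. The highest genes by rule were Gzma (6.70, on 308 against 2 UMIs), Dntt (5.42), Plac8 (3.87), Xcl1 (3.78), Ly6d (3.31), Bcl2a1d, Gadd45b (2.81), Nr4a3, Trib1 (2.48), Bcl2l1, Mir155hg (2.42) and Nrgn (2.29). The lowest included Neurl3 (-1.41), S100a4 (-1.36), Card6 (-1.31), Gsta4 (-1.26), Cd74 (-1.25), S1pr1, Egr1 and Lmo4 (-1.06). After thinning to 3000 UMIs, Gzma was at -0.43. Without cluster 8 Gzma was at 2.23, Dntt at 2.01, Plac8 at 0.87 and Ly6d at 0.98, and Cd74 turned to 0.60.

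The third question was how the Lta-/- cells differed from the Foxp3eGFP cells, as assigned by the deposited hashtag feature names. Lta (chromosome 17, 35203165 to 35205578) was lower in the cells labelled Lta-/-, with 72 UMIs against 509 and a log2 ratio of -2.73 (-3.10 to -2.37). It was detected in 2.85% (2.20 to 3.63) of Lta-/- and 15.3% (13.8 to 16.9) of Foxp3eGFP cells. The labels do not place the deletion relative to the 3' end that is counted, so the remaining UMIs were not read as intact transcript. Ltb, the neighbouring gene for the membrane partner of lymphotoxin alpha, was at -0.049 (-0.090 to -0.0092). Both gate transcripts were lower in Lta-/- cells, Il2ra at -0.39 (-0.51 to -0.27) and Foxp3 at -0.19 (-0.34 to -0.040). Cells with both transcripts made up 7.66% (6.60 to 8.84) of Lta-/- and 9.87% (8.66 to 11.2) of Foxp3eGFP cells, and 3.65% against 5.67% after thinning. The share with Il2ra only was 11.9% against 14.3%, which became 11.3% against 11.8% after thinning. Foxp3 only cells made up 10.9% and 11.5%, and cells with neither 69.5% and 64.4%.

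The Ccr9-high cluster 3 and the unnamed cluster 7 held larger shares of the Lta-/- cells, and the proliferating-like cluster 6 a smaller one. Cluster 3 took 9.27% (8.10 to 10.5) of Lta-/- and 4.44% (3.62 to 5.38) of Foxp3eGFP cells, a ratio of 2.09. Cluster 7 took 7.26% (6.22 to 8.42) and 3.85% (3.08 to 4.74), a ratio of 1.89. Cluster 6 took 4.59% (3.76 to 5.54) and 7.06% (6.03 to 8.21), a ratio of 0.650. Clusters 0, 1, 2, 4, 5 and 8 had ratios between 0.821 and 1.19, and the mature Treg-like cluster 5 held 448 of 2244 Lta-/- and 479 of 2209 Foxp3eGFP cells. Of the 10 leading genes, 0 in clusters 3 and 6 and 4 in cluster 7 differed at least 1.5-fold between the genotypes within the cluster. One of the latter was Gzmc, with 233 UMIs in Lta-/- and 2 in Foxp3eGFP cells of cluster 7. These are summed UMIs, which a few cells could carry. The sizes of clusters 2, 3 and 7 rested on the clustering. The log2 share ratio of cluster 2, at 0.25, turned to -0.23 with 20 principal components and to -0.087 with the stricter cell filter. With 256 genes that differ or might differ between the genotypes left out of the clustering, the best matches of clusters 3 and 7 had log2 share ratios of 0.51 in place of 1.06 and 0.49 in place of 0.92. The match for cluster 6 was at -0.62 in both.

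**Figure D2:**
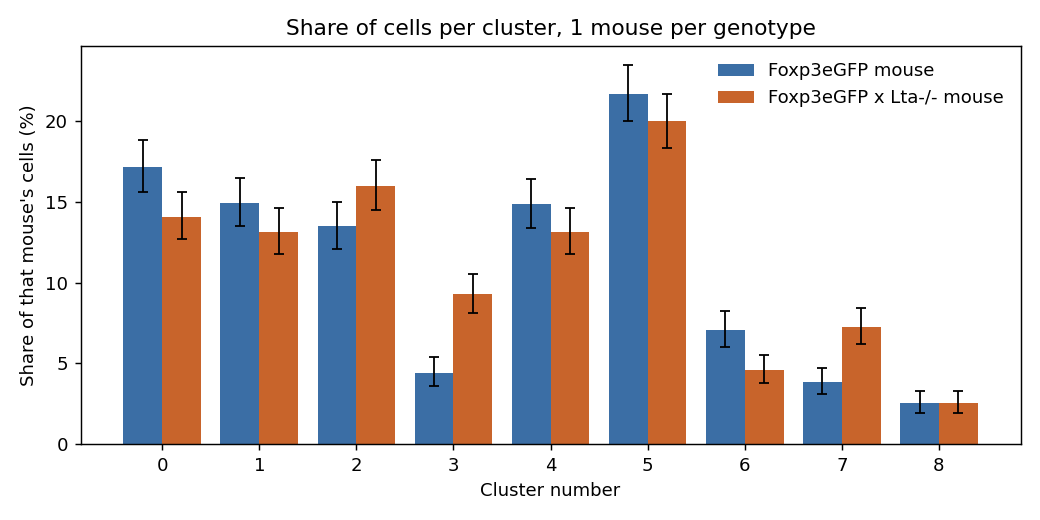
Share of each mouse's cells in the 9 clusters, in percent, as bars with exact 95% binomial intervals that cover counting error only. Cluster 3 held 9.27% of Lta-/- and 4.44% of Foxp3eGFP cells, and cluster 6 held 4.59% and 7.06%.

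Interferon response genes were lower in Lta-/- cells. The list had a log2 ratio of -0.40 (-0.42 to -0.38), with 8 of 20 members at least 1.5-fold lower, 0 higher, and a median of -0.45 that lay at percentile 0 of 10000 random lists matched on expression. Rsad2, an antiviral effector, was at -1.07 (-1.32 to -0.82), Ifit3 at -0.85, Usp18 at -0.84, Ifit1 at -0.80 (-0.90 to -0.70) and Isg15 at -0.79 (-0.86 to -0.72). The interferon-gamma associated Gbp2 and Gbp4 were at 0.047 and -0.045. Within clusters, the list was lower in Lta-/- cells in each of clusters 0 to 7, from -0.87 in cluster 6 to -0.18 in cluster 5, and higher only in cluster 8, at 0.38. It was lower in each class by transcript, at -0.47 in Foxp3 only, -0.26 in Il2ra only, -0.33 in both and -0.42 in neither. Proliferation genes were lower as well, at -0.50 (-0.52 to -0.49), with 9 of 20 members lower, among them Rrm2 at -0.89, Top2a at -0.80 and Mki67 at -0.64. Without cluster 6 the list was at -0.42, and the mean of its within-cluster ratios over clusters 0 to 7 was -0.15. Among single clusters it was lowest in cluster 8, at -0.63, and cluster 4, at -0.42, of which cluster 8 had all 12 proliferation markers higher. Within classes it was lower in Il2ra only (-0.76), both (-0.64) and neither (-0.58), and higher in Foxp3 only (0.31).

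**Figure D3:**
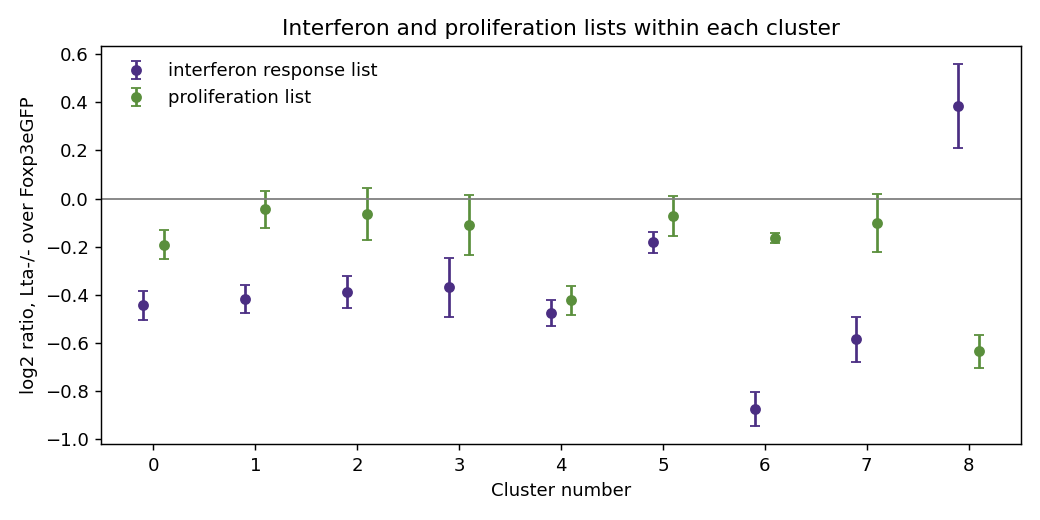
Log2 ratio of the interferon response and proliferation lists, Lta-/- over Foxp3eGFP cells, within each cluster, with exact 95% counting intervals. The interferon list lay between -0.87 and -0.18 in clusters 0 to 7 and at 0.38 in cluster 8.

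Of the effector and recirculating Treg list, 7 of 20 measured members were at least 1.5-fold higher in Lta-/- cells and 0 lower. Il1r2 was at 1.52 (0.89 to 2.19), Cxcr3 at 0.99 (0.64 to 1.33), S100a6 at 0.98 (0.84 to 1.12), Ahnak at 0.88, Itgb1 at 0.64 and Maf at 0.63. Cxcr3, S100a6 and Maf were also leading genes of cluster 7, and within that cluster they were at 0.51, 0.30 and 0.097. The sum was at 0.075 (0.054 to 0.096), and its members Vim and Crip1 were at 0.070 and -0.26. Within clusters it was highest in the mature Treg-like cluster 5, at 0.31 (0.25 to 0.36), against 0.11 (0.055 to 0.16) in cluster 7. By transcript, it was at 0.37 (0.30 to 0.45) in cells with both, 0.047 (-0.021 to 0.11) in Foxp3 only, 0.053 (-0.0081 to 0.11) in Il2ra only and 0.033 in neither. The sort had removed CCR6+ cells, and Ccr6 was at -0.038 (-0.56 to 0.48). The Treg core list was at -0.12 (-0.14 to -0.097) with 0 of 19 members past 1.5-fold, from -0.39 for Il2ra to 0.42 for Izumo1r, the folate receptor 4 gene. The TNFR superfamily and NF-kB list, which holds the receptor genes Tnfrsf1a, Tnfrsf1b and Tnfrsf14 among others, was at -0.14 (-0.16 to -0.12) with 0 of 20 past 1.5-fold. The strong T cell receptor signal list was at -0.0027 (-0.023 to 0.018). The IL-4 and STAT6 list was at -0.045 and its median at 0.025, so sum and median differed in sign, and Il4ra was at 0.092 (-0.093 to 0.28). Other lists were at 0.14 for helper lineage regulators, 0.13 for immature CD4 thymocyte genes, -0.0013 for chemokine receptors, -0.028 for IL-2 and STAT5, -0.037 for maturation and egress and -0.073 for apoptosis. The lymphotoxin and TNF ligand and the dissociation stress lists were at -0.054 and -0.057, with medians of 0.12 and 0.014. The median log2 ratio over all genes compared was 0.0041.

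**Figure D4:**
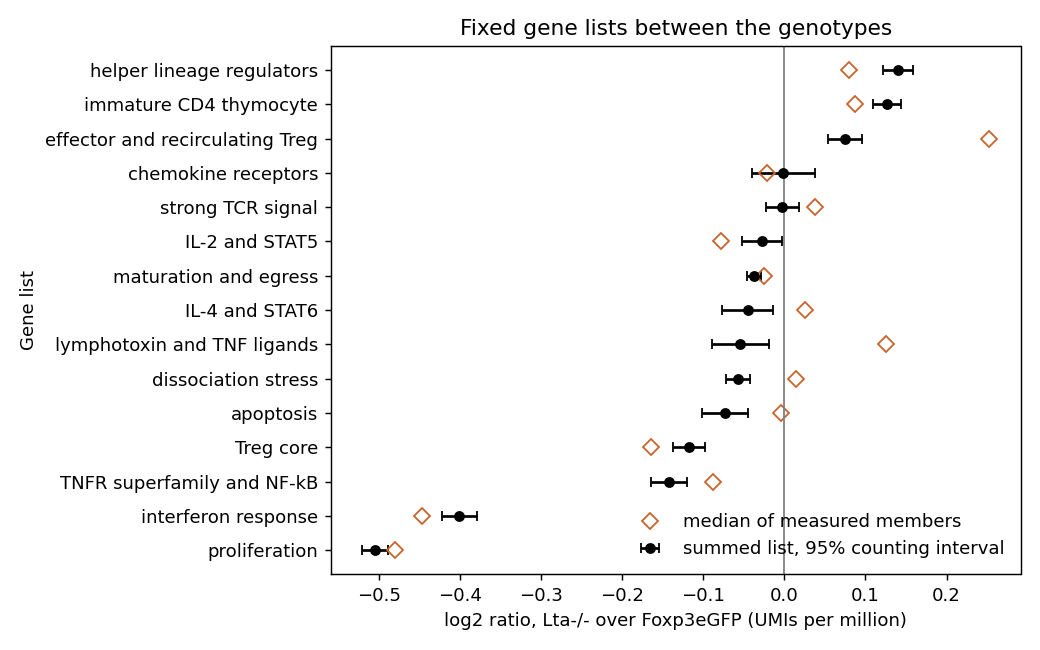
Log2 ratio of the 15 fixed gene lists, Lta-/- over Foxp3eGFP cells, as the summed list with its 95% counting interval (black) and the median of measured members (open diamonds). The interferon response list at -0.40 and the proliferation list at -0.50 lay lowest.

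By the fixed rule, the highest genes in Lta-/- cells were Dnah8 (1.38, 1.27 to 1.48), Glo1 (1.36, 1.27 to 1.45), S100a6 (0.98), H2-Q7 (0.91, 0.85 to 0.98), Itgb1 (0.64), Id2 (0.48), Il7r (0.46), Gng2 (0.46), Cirbp (0.46), AC149090.1 (0.45), Cd69 (0.45) and Ctsb (0.44). Id2 and Il7r were also leading genes of the larger cluster 3. The lowest were Iglc2 (-9.39), Igha (-6.81), Jchain (-5.85) and Igkc (-4.84), then Penk (-2.70), Plac8 (-1.62), Ly6k (-1.26), Lyz2 (-1.25), Xcl1 (-1.15), Knl1 (-0.98), Ifi208 (-0.96) and Spc25 (-0.91). The immunoglobulin genes rested on 2 Foxp3eGFP cells of cluster 8 with at least 100 such UMIs each, of which the top cell held 44.9% of all 16095, and without cluster 8 Iglc2 was at 0.071, Igha at 0.34, Jchain at -0.032 and Igkc at 0.49. Of the Lyz2 UMIs, cluster 8 held 373 of 378 in Lta-/- and 944 of 958 in Foxp3eGFP cells, and within it the macrophage gene C1qb was at 2.13 (1.62 to 2.67). Penk, which encodes proenkephalin, was at -2.75 (-3.01 to -2.49) without cluster 8 and had 0 UMIs in Lta-/- cells of cluster 0 against 457 in Foxp3eGFP cells. The Penk UMIs are sums as well, which a few cells could carry. Markers of gamma-delta T cells (-1.02, on 550 against 1188 UMIs) were lower in Lta-/- cells. Of these 8 markers, 4 were higher in cluster 6, 4 in the mixed cluster 8 and 5 in cluster 7. The shares of Lta-/- cells in those clusters were smaller, alike and larger, so the ratio is not a count of gamma-delta T cells. Markers of B cells were at -1.01, with Iglc2 giving 3594 of their 6125 UMIs in Foxp3eGFP and 5 of 2841 in Lta-/- cells. Those of NK cells or innate lymphoid cells were higher (0.27). Id2 alone, named above as a leading gene of cluster 3, gave 1676 of their 2905 UMIs in Lta-/- and 1283 of 2579 in Foxp3eGFP cells. The other cell type marker lists were at -0.12 for mature Treg, 0.022 for agonist-signalled precursors, 0.00073 for mature and 0.17 for immature CD4 single-positive cells, 0.16 for effector or recirculating Treg, -0.55 for proliferating and -0.49 for interferon-responding cells. Double-positive thymocyte markers were at -0.17, CD8 T at 0.12, innate-like T at -0.29, myeloid or dendritic at 0.11, thymic epithelial at -0.064, stromal or endothelial at 0.094 and erythroid at -0.055.

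Dnah8 (chromosome 17, 30626935 to 30875762), Glo1 (30592861 to 30612659), which encodes the methylglyoxal-detoxifying glyoxalase, and H2-Q7 (35439140 to 35443773), a class Ib major histocompatibility gene, lie within 10 Mb of Lta. Those 3 of the 12 highest genes compare with 2.41% (70 of 2901) of the genes that could have been named. Glo1 was higher in Lta-/- cells in every cluster, from 0.81 in cluster 8 to 1.70 in cluster 6. H2-Q7 ranged from 0.53 in cluster 4 to 2.17 in cluster 8, except in cluster 6, at 0.088 (-0.12 to 0.29), and cluster 3, at -0.89 (-2.02 to 0.26). H2-Q7 shares sequence with its H2-Q neighbours.

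**Figure D5:**
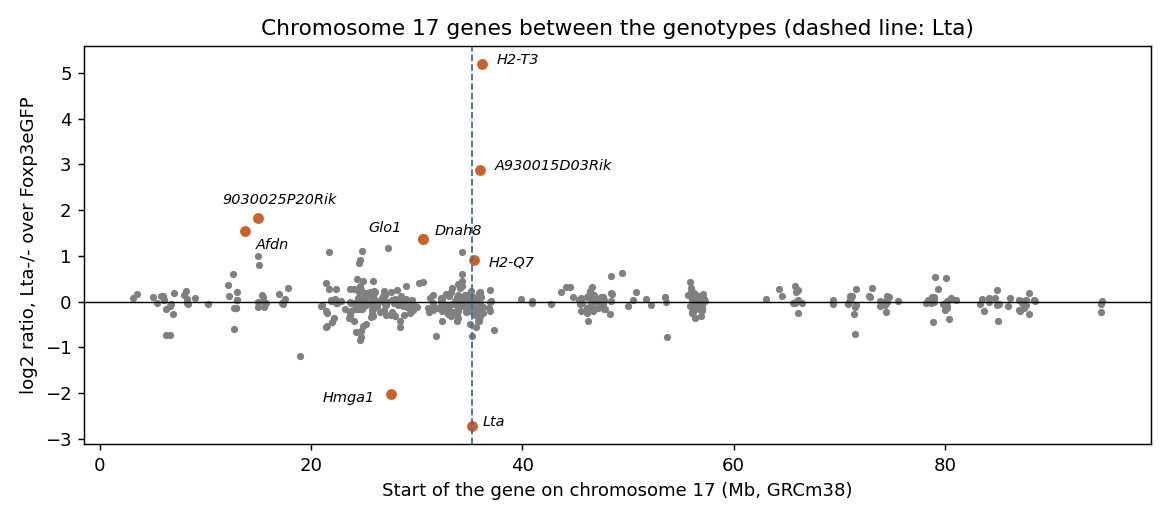
Log2 ratio, Lta-/- over Foxp3eGFP cells, of each chromosome 17 gene with at least 100 UMIs against the gene's start in Mb, with the genes named in the text in orange and the position of Lta as a dashed line. Glo1 and Dnah8 lay at 1.36 and 1.38, Lta at -2.73, and H2-T3, chosen after its value was seen, at 5.20.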

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

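Chosen only after the result was seen were the within-cluster tests of the interferon list and of Glo1, the comparison of clusters low in the gate genes, and the count of mice. The tests of depth, of responding cells, of the genes around Lta and of the H2-Q sum were chosen before.

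The proliferation list went opposite ways in the cells of the 2 mice. For Foxp3 only over both, its log2 ratio was -0.088 in Foxp3eGFP and 0.86 in Lta-/- cells. For Il2ra only over Foxp3 only, it was 0.76 in Foxp3eGFP and -0.31 in Lta-/- cells. The IL-2 and STAT5 list, Il2ra only over Foxp3 only, was at -0.18 in Foxp3eGFP and 0.080 in Lta-/- cells. With 1 mouse per genotype, none of these differences between the mice was tested. The 184 cells that carried both hashtags were used in no genotype comparison, though they were kept in the comparisons by Foxp3 and Il2ra.

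The interferon response list was lower in Lta-/- cells, at a log2 ratio of -0.40. A shift between clusters would need the within-cluster ratios to shrink, but their mean over clusters 0 to 7 was -0.47 and all 8 were below 0. Depth per cell argues no better, since the ratio was -0.44 with every cell at 3000 UMIs. A few strongly responding cells would leave the median cell alike, whereas the median Lta-/- cell held 71.4% of the list's UMIs of the median Foxp3eGFP cell (5 against 7) after thinning. With 1 mouse per genotype, a loss of lymphotoxin alpha cannot be told apart from another difference between these animals, such as an infection, litter or housing, and may or may not be the cause.

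Glo1, Dnah8 and H2-Q7, all near Lta, were higher in Lta-/- cells. If DNA of another mouse strain came along with the targeted allele, other genes around it would differ too, and the median absolute log2 ratio of the 209 other genes within 10 Mb was 0.12, at percentile 99.1 of 10000 random lists matched on expression (median 0.095). Interferon-inducible genes of this region do not carry that result, as the percentile was 98.8 without H2-, Psmb and Tap genes. Cluster composition would bring the within-cluster ratios to 0, but the lowest of Glo1 in clusters 0 to 7 was 0.88, and H2-Q7 was at 0.53 to 2.17 within 7 clusters, though at 0.088 in cluster 6 and -0.89 (-2.02 to 0.26) in cluster 3. Reads that only moved between H2-Q copies would leave the summed H2-Q UMIs alike, but their ratio was 0.50 (0.45 to 0.55). That argues against such a move, though H2-Q7 itself made up most of the sum. How reads that fit several copies were counted is not known, so shared reads otherwise stay open for H2-Q7. Strain DNA is a candidate explanation, so differences in this region may not reflect the loss of lymphotoxin alpha.

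The Ccr9-high cluster held a larger share of Lta-/- cells. A leak of cells without the gate genes through the sort of that mouse stays open: 1 of the 2 other clusters low in Foxp3 and Il2ra, cluster 6, held a smaller share, but this was known when the test was written and cluster 4 was undecided (-0.18, -0.41 to 0.056). Cells with neither transcript made up 69.5% of Lta-/- and 64.4% of Foxp3eGFP cells, and Il2ra and Foxp3 were at -0.39 and -0.19, which a leak would also give. Depth did not set the share, whose ratio among cells of at least 3000 UMIs was 2.15 (9.61% against 4.46%). The number of mice per genotype was 1, so genotype cannot be told apart from another difference between the mice or their sorts.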

How the results depend on the processing

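With 1 mouse per genotype and 1 capture, no spread between animals could be measured. Depth limited detection, with Foxp3 found in 20.5% of cells and in 13.4% after thinning to 3000 UMIs. No paired analysis was possible because each genotype had 1 mouse. The comparisons of cells from 1 mouse alone or with 1 hashtag, the within-cluster mean, the list without its most abundant member, the clusters matched between clusterings, and the median of members, cluster 6 and cluster 8 alternatives for the genotype comparison were chosen after seeing the data. Under all alternatives tried, Lta stayed lower in Lta-/- cells, at log2 ratios from -2.62 to -2.81, the interferon list from -0.36 to -0.47 and the cluster 6 share from -0.62 to -0.78. Of the values for the questions asked, 131 stayed within their counting interval, 67 moved further and 1 turned. Of the other values, 1087 stayed, 370 moved and 47 turned. Given next are the values for the questions asked that left their interval and all values that turned, as log2 ratios where not in percent, with "opposite" for a turned direction; the cause was not tested.

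With cells thinned to 3000 UMIs, the shares were Foxp3 only 8.65%, Il2ra only 11.6%, both 4.72%, neither 75.0%. After thinning, for Il2ra only over both, T cell receptor signal 0.33, egress -0.29, Gzma -1.30 (opposite). After thinning, for Foxp3 only over both, T cell receptor signal -0.046, egress 0.034, chemokine receptors -0.063 (opposite), proliferation -0.083 (opposite), H2afx -0.22 (opposite), Ube2c -1.20 (opposite), Hist1h2ap -2.20 (opposite), Hist1h1b -0.55 (opposite). After thinning, for Il2ra only over Foxp3 only, T cell receptor signal 0.38, IL-4 0.060 (opposite), lymphotoxin 0.0022 (opposite), egress -0.32, Gzma -0.43 (opposite). After thinning, for Lta-/- over Foxp3eGFP, interferon -0.44. When a class needed 2 UMIs, the shares were Foxp3 only 4.10%, Il2ra only 6.47%, both 3.02%. At 2 UMIs, for Il2ra only over both, T cell receptor signal 0.28, egress -0.52. At 2 UMIs, for Foxp3 only over both, T cell receptor signal 0.055 (opposite), egress 0.054, proliferation -0.44 (opposite), Ube2c -1.45 (opposite), Hist1h1b -0.55 (opposite). At 2 UMIs, for Il2ra only over Foxp3 only, T cell receptor signal 0.22, egress -0.58, Cd74 0.84 (opposite). Without cluster 8, for Il2ra only over both, T cell receptor signal 0.28, egress -0.32. Lacking cluster 8, for Il2ra only over Foxp3 only, T cell receptor signal 0.40, egress -0.41, proliferation -0.068 (opposite), Cd74 0.60 (opposite). Lacking cluster 8, for Lta-/- over Foxp3eGFP, proliferation -0.47, interferon -0.43, Iglc2 0.071 (opposite), Igha 0.34 (opposite), Igkc 0.49 (opposite). Without cluster 6, for Il2ra only over both, egress -0.36. Lacking cluster 6, for Foxp3 only over both, egress 0.11, Ube2c -0.59 (opposite). Lacking cluster 6, for Lta-/- over Foxp3eGFP, proliferation -0.42, interferon -0.36. In cells with 1 hashtag, for Il2ra only over Foxp3 only, T cell receptor signal 0.37. In Foxp3eGFP cells alone, the shares were Il2ra only 14.3%, neither 64.4%. Foxp3eGFP cells gave for Il2ra only over both, egress -0.48, effector 0.0052 (opposite). Foxp3eGFP cells gave for Foxp3 only over both, T cell receptor signal -0.067, egress 0.12, proliferation -0.088 (opposite), Hist1h1b -0.0089 (opposite). Foxp3eGFP cells gave for Il2ra only over Foxp3 only, T cell receptor signal 0.26, egress -0.60. In Lta-/- cells alone, the shares were Il2ra only 11.9%, both 7.66%, neither 69.5%. Lta-/- cells gave for Il2ra only over both, T cell receptor signal 0.28, egress -0.29, apoptosis 0.079 (opposite), Hist1h1b -0.71 (opposite). Lta-/- cells gave for Foxp3 only over both, T cell receptor signal -0.23, egress 0.071, effector -0.060 (opposite), S100a4 -0.14 (opposite), Xcl1 3.28 (opposite). Lta-/- cells gave for Il2ra only over Foxp3 only, T cell receptor signal 0.50, IL-4 0.041 (opposite), egress -0.36, proliferation -0.31 (opposite), Cd74 0.34 (opposite). As a mean over cells, for Il2ra only over both, T cell receptor signal 0.32, egress -0.29, apoptosis 0.0064 (opposite). The cell mean gave for Il2ra only over Foxp3 only, T cell receptor signal 0.44, IL-4 0.0080 (opposite), egress -0.38. As a median of list members, for Il2ra only over both, T cell receptor signal 0.17, egress -0.47, apoptosis 0.053 (opposite), effector 0.044 (opposite), helper 0.25 (opposite), chemokine receptors 0.77 (opposite). The member median gave for Foxp3 only over both, T cell receptor signal -0.44, egress 0.12. The member median gave for Il2ra only over Foxp3 only, T cell receptor signal 1.20, IL-4 0.031 (opposite), lymphotoxin 0.62 (opposite), egress -0.65, chemokine receptors 0.061 (opposite). The member median gave for Lta-/- over Foxp3eGFP, IL-4 0.025 (opposite), lymphotoxin 0.12 (opposite), proliferation -0.48, interferon -0.45, dissociation stress 0.014 (opposite). At resolution 1.0, there were 17 clusters. At a hashtag share of 90%, for Lta-/- over Foxp3eGFP, Igkc 0.54 (opposite). As a mean of within-cluster ratios, for Lta-/- over Foxp3eGFP, proliferation -0.15, interferon -0.47. Without the most abundant member of each list, for Lta-/- over Foxp3eGFP, interferon -0.45. At resolution 0.3, for Lta-/- over Foxp3eGFP, cluster 3 share 0.62. With 20 principal components, for Lta-/- over Foxp3eGFP, cluster 2 share -0.23 (opposite), cluster 3 share 0.63. With genes that differ by genotype left out of the clustering, for Lta-/- over Foxp3eGFP, cluster 3 share 0.51, cluster 7 share 0.49. With the looser cell filter, for Lta-/- over Foxp3eGFP, cluster 2 share -0.23 (opposite), cluster 3 share 0.51. With the stricter cell filter, for Lta-/- over Foxp3eGFP, cluster 2 share -0.087 (opposite).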

Other observations

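Genes far from one another on chromosome 17 also differed between the mice. All genes of this paragraph other than Lta, Glo1 and Dnah8 were chosen after their values were seen. H2-T3 (chromosome 17, 36185571 to 36190151), which encodes the thymus leukaemia antigen, a class Ib molecule whose thymic expression differs between inbred strains, had 103 UMIs in Lta-/- and 3 in Foxp3eGFP cells (log2 ratio 5.20, 3.61 to 7.50). The nearby noncoding gene A930015D03Rik was at 2.87 (2.28 to 3.51). On the other side of Glo1 and Dnah8, Hmga1 (27556574 to 27563672), an architectural chromatin protein gene, was at -2.03 (-2.58 to -1.52). Farther out, beyond 10 Mb from Lta, Afdn (13760391 to 13905798) was at 1.54 (1.15 to 1.94) and 9030025P20Rik (14978864 to 14991577) at 1.83 (1.41 to 2.26). Chromosome 17 ranked 1 of 20 chromosomes by the 90th percentile of absolute log2 ratios, at 0.43, followed by chromosome X at 0.39. Both also had the lowest median UMIs per gene of all chromosomes, at 668 and 674. Low counts widen such ratios, and the ranking was not matched on expression. Along chromosome 17, that percentile was 0.27 from 0 to 10 Mb, 1.05 from 10 to 20 Mb, 0.51 from 20 to 30 Mb and 0.44 from 30 to 40 Mb. In the bins from 40 Mb on it was between 0.19 and 0.29.

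Among chemokine receptors of cells by gate transcript, Gpr183, the receptor for oxysterols that guides T cells, was at 1.12 (0.91 to 1.33) in Il2ra only over both and at 1.89 (1.63 to 2.16) in Il2ra only over Foxp3 only. Ccr8 had 46 of 4357492 UMIs in Il2ra only cells, against 11 of 2942031 in cells with both and 9 of 2936598 in Foxp3 only cells. These raw sums come from pools of unlike size and overstate the difference per UMI. Cxcr3 was at 1.76 (0.93 to 2.66) in Foxp3 only over both. Of the immature CD4 thymocyte genes, 5 were at least 1.5-fold higher in Il2ra only over both, among them Cd24a at 2.34 (1.75 to 2.97), Itm2a at 1.25 (1.14 to 1.36) and Sox4 at 1.08 (0.91 to 1.26), while 0 of 14 measured members were at least 1.5-fold lower. The summed list was at 0.22 (0.19 to 0.26). Cd24a was higher in the mixed cluster 8, which held 30 of the 615 Il2ra only cells and 1 of the 426 with both. Its ratio may rest partly on those cells. Cd24a, Itm2a and Sox4 were all higher in cluster 0, which held 187 Il2ra only cells and 30 with both. In the Foxp3eGFP mouse, Lta was at 82.8 CPM in the mature Treg-like cluster 5 (222 UMIs), 46.3 in cluster 1 and 11.3 in cluster 3. Ltb was at 1219 CPM in cluster 5 and 336 in cluster 3.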
